A study of Drosophila virilis and Drosophila yakuba with 2 samples.

How the data were processed

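Heads of mated wild-type females were dissected, RNA was extracted with Trizol, and 1 µg of total RNA per species went into a stranded total RNA library, per the labels' protocols. The authors deposited 1 table of FPKM values per library, with a gene identifier, a gene name, a locus and the FPKM in each line, per the file headers. TopHat and Cufflinks were named as the tools, per the submitters' processing notes; their versions, the genome builds, the annotation releases and the use of strand in assigning reads are not given in the sources used here. FPKM divides fragments by model length and library total, so values of species with different annotations also depend on how complete the gene models are. The tables gave no confidence intervals and no fragment counts.

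Each library was taken as its own group, virilis or yakuba, with 1 library per species and therefore no test, p-value or replicate error. Species, annotation, read mapping and library preparation cannot be separated in this design. All gene models were kept, including those listed at 0. Locus starts counted from 0, since end minus start was a multiple of 3 for 66.8% of virilis and 67.6% of yakuba spans under 900 bp against 33.3% by chance, and starts are given counted from 1.

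Depth was estimated after the values had been examined. For models with spans of 900 to 4000 bp, divisible by 3, and FPKM under 0.12, the total and the fragment length were searched for the pair that brought the largest share of values within 0.04 of a whole number of fragments, up to 6.5 fragments. The share was 58.9% in virilis with a fragment length of 160 bp and 49.0% in yakuba with 175 bp, against medians of 6.04% and 6.27% over the searched pairs. A total at a whole fraction of the best was taken instead if its share was nearly as large. Near-best fits were those with at least 90% of the best share and a total close to the chosen one. Their ranges therefore leave out other multiples of the total by construction. On simulated values with a total of 50000000 fragments, the estimate was 49750000 for the 14491 virilis models and 50250000 for the 16077 yakuba models. The simulation made a set share of the models intronless, and the real share is not known.

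Genes were recognised by symbol only. Symbols were carried by 279 virilis models (1.93%) and 497 yakuba models (3.09%), and all others had systematic identifiers that the tables do not pair with names. The gene table supplied with the data was of another D. virilis assembly and matched 0 of the identifiers, so it was not used. Genes were paired between species where the symbol was identical. Genes with a symbol were more highly expressed than the rest in yakuba (median 23.7 FPKM), so list percentiles were computed both among all genes and among genes with a symbol.

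The comparisons, the 26 gene lists by D. melanogaster symbol and the main settings were fixed before the data were examined. Within a library, a list's median FPKM was placed among 10000 random lists of the same size from all genes of that library. Lists with at least 3 members found, 10 in virilis and 15 in yakuba, were given a percentile, and 9 and 5 lists had no member. Only part of most lists was found. Of 36 phototransduction symbols, 4 were found in virilis and 3 in yakuba, and of 26 muscle symbols, 5 and 10. A list percentile therefore describes the members found and not a whole pathway. Between species, log2((FPKM + 1)/(FPKM + 1)) was centred on the median of pairs at 1 FPKM or more in both libraries, and a list's median was placed among 10000 random lists of pairs matched on decile of mean expression. With so few pairs, the smallest pool to draw from held 7 genes, and the random lists could draw a list's own genes. A gene counted as past the rule at 4-fold or more from the median ratio with at least 10 FPKM in the higher library. On simulated pairs with mean levels taken from the 77 pairs, 10 of 10 genes changed 8-fold were called with 0 false calls. Of 10 changed 3-fold, 0 were called. The changed genes were drawn from higher levels only. The simulated noise was far smaller than the spread of the real ratios, whose log2 SD was 1.22 at 10 FPKM or more. The calls at 8-fold and 3-fold and the absence of false calls were therefore fixed in advance. They give neither a detection rate nor an error rate for the rule.

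Genes were named by a rule: the 10 highest models of each library, of which at most the first without a symbol is named, the 15 pairs with the largest ratio in each direction at 10 FPKM or more in the higher library, and for each list the 2 to 4 members with the highest mean FPKM and any member past 4-fold. Some other members, such as the lowest of a list, were named after their values were seen. Chromosome arms were compared by the share of genes at 1 FPKM or more and the median FPKM of those genes, with ratios of medians resampled over genes 2000 times. Virilis scaffolds were assigned by the yakuba chromosome of their paired symbols, which was decided after the data were examined.

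Alternatives were pseudocounts of 0.1 and 5 FPKM, no centring, centring on the ribosomal protein genes, rescaling to TPM, other minimum levels and pairs with spans within 1.5 times of each other. Leaving out models under 300 bp, unmatched random lists, random lists of genes with a symbol and older spellings of symbols were added after the data were examined. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.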

Results

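Gene expression was profiled in the heads of mated wild-type females aged 2 to 5 days, with 1 total RNA library from Drosophila virilis and 1 from Drosophila yakuba. D. yakuba belongs to the same species subgroup as D. melanogaster, and D. virilis is a more distant relative in another subgenus. Each library gave 1 value for each gene model in FPKM, the number of fragments per kilobase of model scaled to the library total, 14491 models in virilis and 16077 in yakuba. At least 1 FPKM was reached by 10305 models (71.1%) in virilis and by 10560 models (65.7%) in yakuba, while 893 models (6.16%) and 1704 models (10.6%) were listed at 0. The median over all models was 6.26 FPKM in virilis and 4.20 FPKM in yakuba, and the 100 highest models held 33.0% and 32.4% of the summed FPKM. With no replicate library in either species, no value below has a replicate error and no difference between the species was tested.

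Low FPKM values fell on steps of whole fragments, and the size of the steps gave the total to which each library had been scaled. This estimate was 70750000 fragments in virilis, with near-best fits from 70000000 to 72750000, and 63000000 fragments in yakuba, with near-best fits from 61250000 to 64500000. By this estimate the virilis total was 1.12 times that of yakuba, which could not be checked against read counts. At these totals a gene at 10 FPKM with 1 kb of effective length stood for 707.5 fragments in virilis and 630 in yakuba, giving 95% exact Poisson intervals of 9.28 to 10.8 FPKM and 9.23 to 10.8 FPKM. A floor of 3 fragments over 1 kb corresponded to 0.0424 FPKM in virilis and 0.0476 FPKM in yakuba. These intervals and floors cover counting error only.

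**Figure D1:**
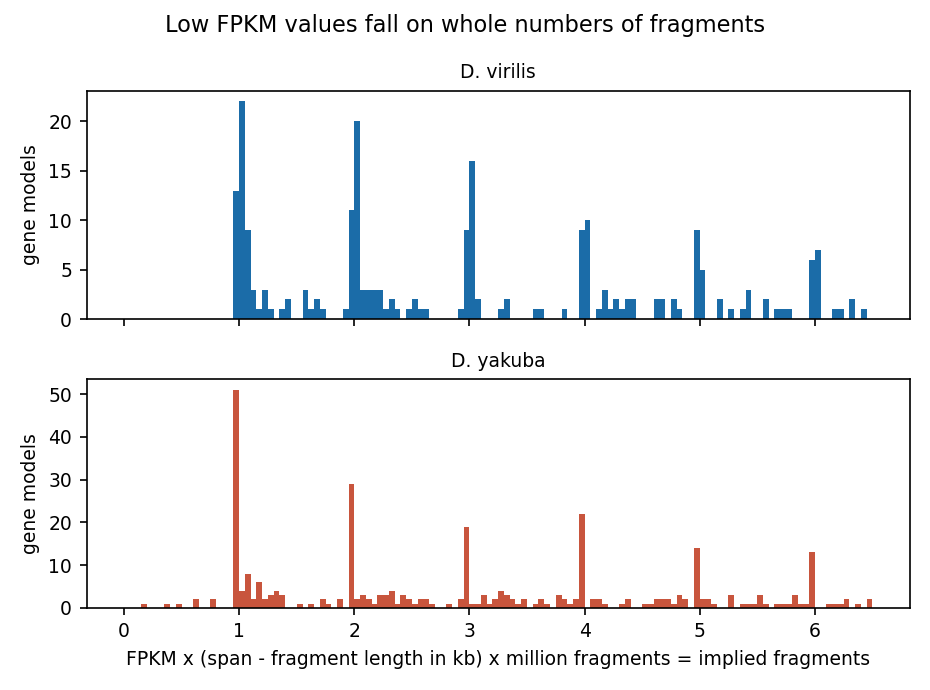
Number of gene models (y axis) by the number of fragments that a low FPKM value implied (x axis: FPKM times the span less the fragment length in kb, times the estimated total in units of 1000000 fragments), for virilis above and yakuba below. Values gathered at whole numbers, with 58.9% of 231 virilis values and 49.0% of 312 yakuba values within 0.04 of one.

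In the virilis heads, the genes found of vision, muscle and the ribosome and some genes of odorant binding were high. The list of egg production genes had a low median. The highest gene with a symbol was ninaE, which encodes the rhodopsin of the outer photoreceptors, at 8636 FPKM (FBgn0013133, scaffold_12855, 7414653 to 7416076). The odorant-binding protein genes Obp44a and Obp56d followed at 4081 and 3649 FPKM. The highest value of all, 16468 FPKM, belonged to GJ18607 (FBgn0205764, scaffold_12823, 1928967 to 1929171), a model of 205 bp that is not much longer than the estimated fragment length of 160 bp. Of the 10 highest models, 7 had a systematic identifier without a symbol, and their functions were not analysed here.

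The 4 phototransduction genes with a symbol in virilis had a median of 173 FPKM, above 99.8% of 10000 random gene lists of the same size. The rhodopsin genes Rh3 and Rh4 stood at 178 and 168 FPKM and Rh2, the rhodopsin of the ocelli, at 62.9 FPKM. The 12 olfactory and chemosensory genes had a median of 101 FPKM (percentile 100), with Obp19d at 722 FPKM and Obp99c at 622 FPKM, and Obp57c was the lowest at 0.192 FPKM. All 40 virilis odorant-binding protein genes with a symbol, a family chosen after the values were seen, had a median of only 9.41 FPKM, and 17 of them were under 1 FPKM. All 5 muscle genes were above 100 FPKM, with a median of 464 FPKM (percentile 100): the myosin light chain gene Mlc1 reached 1685 FPKM, the myosin heavy chain gene Mhc 1181 FPKM, and the troponin genes wupA and up 464 and 383 FPKM. The 6 ribosomal protein genes lay between 552 and 977 FPKM (median 781, percentile 100). The yolk protein gene Yp1, transcribed in the female fat body, was at 215 FPKM and Obp99b at 73.0 FPKM, while Amyrel in the same list of 3 was at 0.193 FPKM. That list's median was 73.0 FPKM (percentile 98.7), and it was 144 FPKM over the members at 1 FPKM or more.

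Within the virilis library, genes of the clock and of sex determination had lower medians than the lists above. The clock genes tim and per and the clock neuropeptide gene Pdf had 72.1, 22.9 and 12.7 FPKM, with a median of 22.9 FPKM at percentile 88.8. The 8 genes of sex determination and dosage compensation had a median of 5.40 FPKM (percentile 40.5). Sxl, the master regulator of female development in D. melanogaster, led them at 39.3 FPKM, and the courtship gene fru had 11.1 FPKM, against 3.20 FPKM for dsx and 5.55 FPKM for msl-2. The 11 genes of oogenesis and the germline had a median of 0.787 FPKM (percentile 4.69), and 7 of them were under 1 FPKM. The highest of these were the chorion gene Cp15 at 4.04 FPKM and ovo at 3.28 FPKM, and the germline genes vas and nos had 0.246 and 0.0864 FPKM. Among random lists of genes with a symbol, the virilis phototransduction list was at percentile 94.95, the fat body list at 89.7, the clock list at 77.4, the sex determination list at 28.2 and the oogenesis list at 2.22. The 3 genes found of the digestive list, all maltase genes out of 10 with a symbol, had a median of 1.96 FPKM (percentile 26.9, and 19.4 among genes with a symbol), with Mal-A1 the highest of the 3 at 5.78 FPKM. Outside the list, Mal-A5 and Mal-B2 were higher, at 23.3 and 11.3 FPKM. Of the neuronal genes, the sodium channel gene para had 33.2 FPKM, the pan-neuronal gene elav 12.8 FPKM and the dopa decarboxylase gene Ddc 57.2 FPKM. The 3 housekeeping genes spread from Tbp at 3.27 FPKM to RpL32 at 664 FPKM, with a median of 16.4 FPKM at percentile 80.7, and 70.4 among genes with a symbol. Of lists with fewer than 3 members, the chaperone gene Hsp83 had 417 FPKM, the glycerol-3-phosphate dehydrogenase gene Gpdh 203 FPKM, the receptor gene Tl 29.9 FPKM, the eye pigment genes ry and bw 20.5 and 11.1 FPKM, and the neuropeptide gene Crz 4.23 FPKM.

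In the yakuba heads, the genes found of vision, muscle, metabolism and the ribosome were high, as were Nplp2 and Nplp3 of the neuropeptide list. The list of egg production genes again had a low median. The highest gene with a symbol was Nplp2 of the neuropeptide list, at 6117 FPKM (FBgn0068115, 3L, 13445634 to 13446176). Next was the alcohol dehydrogenase gene Adh at 4341 FPKM (FBgn0013162, 2L, 14730546 to 14731445). The metallothionein gene MtnA and the arrestin gene Arr1 followed among genes with a symbol, at 2213 and 2177 FPKM. The highest model, GE25107, had 10338 FPKM (FBgn0242194, 3R, 4483888 to 4485433) and was among the 6 of the 10 highest models that had no symbol. The 3 phototransduction genes were Arr1, the retinal pigment dehydrogenase gene Pdh at 1296 FPKM and chp, which encodes a photoreceptor membrane protein, at 378 FPKM (percentile 100). Besides Nplp2, the neuropeptide list held Nplp3 and Dsk at 958 and 10.9 FPKM, and its median of 958 FPKM was at percentile 100. Only 3 of the 30 neuropeptide symbols were found, so the list does not show that neuropeptide genes as a class were high. The clock genes tim and per had 89.2 and 18.9 FPKM. Other lists had fewer than 3 members. In the hemocyte list, the ferritin gene Fer1HCH had 405 FPKM and Sr-CI 5.39 FPKM. In the fat body list, to, which encodes the fat body protein takeout, had 39.2 FPKM and Amyrel 0.667 FPKM. The neuronal gene fne had 24.5 FPKM, and fru and msl-1 of the sex determination list had 16.7 and 9.72 FPKM.

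The 10 muscle genes of yakuba had a median of 306 FPKM (percentile 100), from TpnC4 at 51.1 FPKM to Mlc2 at 1053 FPKM, with Mlc1 at 605 FPKM and Mhc at 490 FPKM. The 38 ribosomal protein genes lay between 452 and 1681 FPKM (median 918, percentile 100). The oxidative phosphorylation list had 4 of its 39 symbols found, with a median of 642 FPKM (percentile 100). Among them were the adenine nucleotide translocase gene sesB at 2117 FPKM and the mitochondrial pore gene porin at 552 FPKM. ATPsyn-beta at 1382 FPKM, ATPsyn-gamma at 322 FPKM and ND75 at 131 FPKM, which the list holds under other spellings, were not counted. The 8 glycolytic genes had a median of 224 FPKM (percentile 100), led by Gapdh1 at 810 FPKM and the pyruvate kinase gene PyK at 413 FPKM. The 4 olfactory genes had a median of 454 FPKM (percentile 100), with Obp56e at 864 FPKM and the esterase gene Est-6 at 4.25 FPKM. The 6 heat shock genes had a median of 280 FPKM (percentile 100), with the chaperone genes Hsc70-4 at 706 FPKM, DnaJ-1 at 385 FPKM and Hsp68 at 336 FPKM. The 5 housekeeping genes had a median of 810 FPKM (percentile 100), with the calmodulin gene Cam at 1473 FPKM and alphaTub84B at 522 FPKM. The 4 detoxification genes had a median of 74.3 FPKM (percentile 99.4, and 72.3 among genes with a symbol), with GstD1 at 114 FPKM and Sod2 at 106 FPKM. The yakuba lists at percentile 100 were at 95.6 or higher among random lists of genes with a symbol.

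The 12 immune genes of yakuba had a median of 19.2 FPKM, with the serpin gene nec at 95.5 FPKM, the receptor gene Tl at 44.5 FPKM and the transcription factor genes Rel and Dif at 42.3 and 30.1 FPKM. The antimicrobial peptide genes AttA and DptB were at 20.9 and 17.5 FPKM, and AttD was at 0.341 FPKM. Dpt, another antimicrobial peptide gene that the list holds under a different spelling and so did not count, had 62.3 FPKM. The 4 eye pigment genes had a median of 32.7 FPKM, with Hn, which encodes phenylalanine hydroxylase, at 147 FPKM and v at 48.4 FPKM. The 3 genes of RNA interference found were AGO2 at 34.9 FPKM, r2d2 at 11.3 FPKM and Dcr-2 at 9.51 FPKM. These 3 lists were at percentiles 99.1, 96.8 and 77.6 among random lists of all yakuba genes, but at 35.7, 52.9 and 28.5 among random lists of genes with a symbol, whose median was 23.7 FPKM. The 7 digestive genes had a median of 4.57 FPKM (percentile 52.8, and 5.33 among genes with a symbol), with the trypsin gene alphaTry at 46.3 FPKM and the amylase genes Amy-d and Amy-p, near-identical copies whose values are uncertain, at 13.7 and 10.4 FPKM. The 4 genes of oogenesis and the germline had a median of 1.01 FPKM (percentile 16.7, and 1.47 among genes with a symbol), and the highest was the eggshell gene dec-1 at 2.81 FPKM. Over the members at 1 FPKM or more, the digestive median was 10.4 FPKM and the oogenesis median 1.99 FPKM, and the virilis oogenesis median was 2.81 FPKM.

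**Figure D2:**
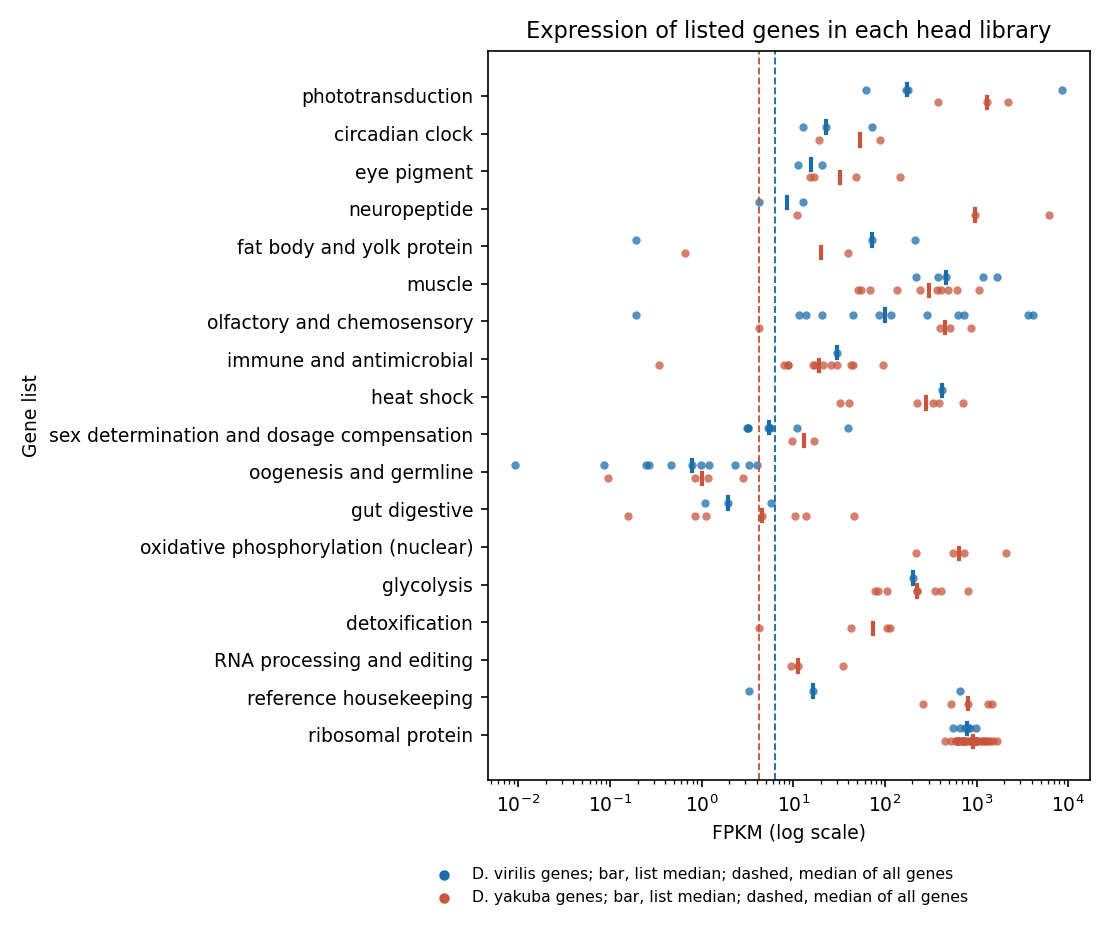
FPKM on a log axis of the listed genes with a symbol in the virilis (blue) and yakuba (red) head libraries, 1 point per gene, with bars at list medians and dashed lines at the medians of all genes, 6.26 FPKM in virilis and 4.20 FPKM in yakuba. Muscle and ribosomal protein genes lay far to the right of these lines in both libraries, and the oogenesis genes lay to the left of them.

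The comparison of virilis with yakuba heads was limited to the 77 genes that carried the same symbol in both tables. Of the 41 pairs at 10 FPKM or more in the higher library, most had similar levels in both, with 33 within 2-fold of the median ratio. The other 36 pairs were under 10 FPKM in both libraries and were not counted here. Past 4-fold, 1 gene was higher in virilis and 3 genes were higher in yakuba. Among the rest of the 41 pairs, the 3 muscle pairs had the largest ratios towards virilis. Ratios are given as log2((virilis + 1)/(yakuba + 1)) in FPKM, relative to the median ratio of the 52 pairs at 1 FPKM or more in both libraries, which was -0.20.

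The gene higher in virilis was the maltase gene Mal-A5, at 23.3 FPKM against 1.96 FPKM (log2 ratio 3.23). The odorant-binding protein gene Obp99a was higher in yakuba, at 395 FPKM against 45.4 FPKM (log2 ratio -2.90), as was dhd, a thioredoxin gene of the female germline, at 22.8 FPKM against 1.77 FPKM (log2 ratio -2.91). MtnC, a metallothionein gene, was listed at 0 in virilis and had 15.7 FPKM in yakuba. The MtnC value is uncertain, since MtnB and MtnC had the same value and the same model length of 193 bp in yakuba, and a model at 0 can be a failed estimate. Only Obp99a was still past 4-fold and higher in yakuba with a pseudocount of 5 FPKM or with a minimum of 30 FPKM, and no gene was past 4-fold and higher in virilis at that minimum. When the ratios were centred on the ribosomal protein genes, 2 genes were past 4-fold in virilis, with wupA added, and 3 in yakuba.

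The muscle pairs wupA, Mlc1 and Mhc had log2 ratios of 1.97, 1.67 and 1.47, with 464, 1685 and 1181 FPKM in virilis against 136, 605 and 490 FPKM in yakuba. Their median of 1.67 was at percentile 98.2 of 10000 random lists of 3 pairs matched on mean expression and at 97.6 of unmatched lists, both of which could draw the muscle genes themselves. Other genes higher in virilis were MtnB at 26.5 against 15.7 FPKM (0.92), with the same doubt over its yakuba value as for MtnC, the photoreceptor ligand gene boss at 92.4 against 61.1 FPKM (0.79), Obp49a at 133 against 106 FPKM (0.53) and the ATP synthase gene ATPsyn-beta at 1710 against 1382 FPKM (0.51). The superoxide dismutase gene Sod (0.49), Obp99c (0.47), per (0.46), bru-3 (0.60), the eye pigment gene ry (0.58), Dscam (0.38) and Oda (0.32) completed the 15 largest ratios towards virilis. This ranking is of pairs at 10 FPKM or more in the higher library. The gene models of per (4886 bp in virilis, 1194 bp in yakuba), Obp99c (533 and 1034 bp), Oda (5994 and 3564 bp) and MtnA (213 and 383 bp) differed in span by over 1.5 times, so their ratios also depend on the models.

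Towards yakuba, the ranking is again of pairs at 10 FPKM or more in the higher library. The next ratios after Obp99a, dhd and MtnC were those of the maltase gene Mal-B2, at 11.3 FPKM in virilis against 35.3 FPKM in yakuba (-1.36), and MtnA, at 1041 against 2213 FPKM (-0.89). The ribosomal protein genes RpL32 (-0.79), RpL15 (-0.53) and RpL14 (-0.32) followed, with cbt (-0.77), Fuca (-0.59), sog (-0.48), Tl (-0.36), fru (-0.36), SREBP (-0.26) and tub (-0.25). The 6 ribosomal protein pairs had a median of -0.17, with 4 below 0 and 2 above, at percentile 13.9 of matched lists. Those lists came from small pools that held these same genes, so the percentile says little. When centred on these genes, their median was 0 by construction. The 3 pairs of the digestive list, Mal-A1, Mal-A6 and Mal-B1, went both ways, from -0.71 for Mal-B1, whose models differed in span by over 1.5 times, to 1.88 for Mal-A1, with a median of 0.39 at percentile 38.7 of matched lists and 81.5 of unmatched lists. All 10 maltase pairs, most of them outside the list, ran from -1.36 for Mal-B2 to 3.23 for Mal-A5. The clock gene tim had 72.1 FPKM in virilis and 89.2 FPKM in yakuba, and per had 22.9 and 18.9 FPKM.

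Across the 77 pairs, log2(FPKM + 1) in virilis and yakuba had a Pearson r of 0.938 and a Spearman rho of 0.891. These correlations are across genes, which are not independent replicates.

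**Figure D3:**
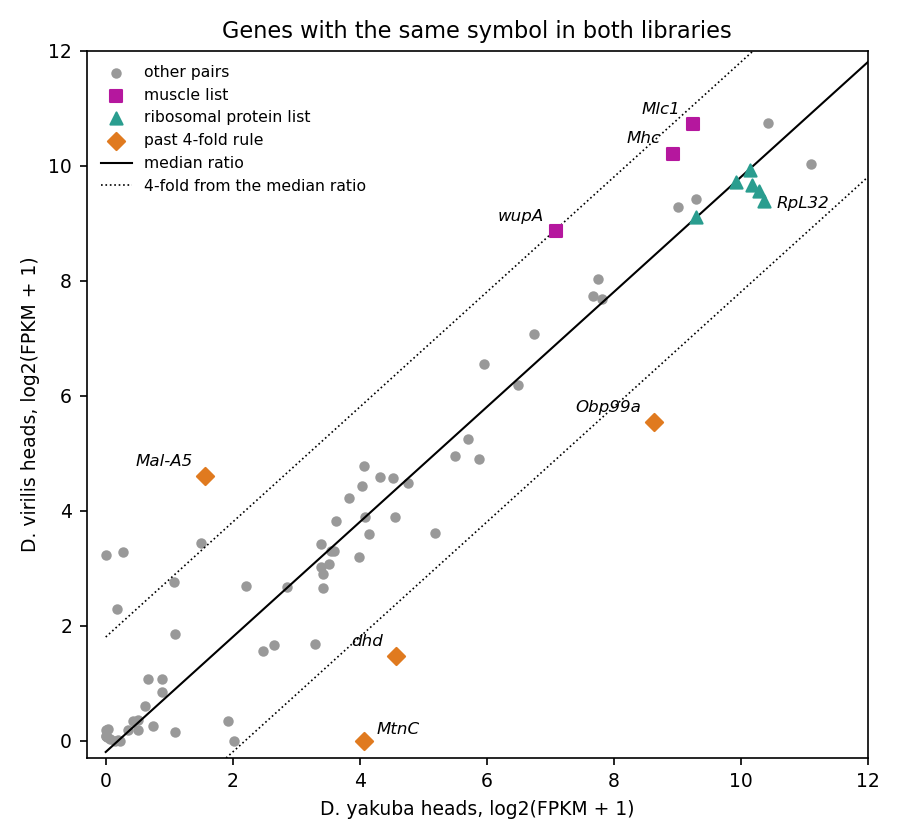
log2(FPKM + 1) of the 77 genes with the same symbol in yakuba (x axis) and virilis (y axis), 1 point per gene, with the median ratio as a solid line and 4-fold from it as dotted lines. The 3 muscle genes lie above the solid line.

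Levels were nearly even across the named chromosome arms of yakuba except on chromosome 4, the small dot chromosome, where genes were more often expressed and had higher FPKM. On chromosome 4, 78 of 82 genes (95.1%) had at least 1 FPKM, and their median was 41.6 FPKM, with a quartile range of 20.9 to 74.7 FPKM. On the arms 2L, 2R, 3L and 3R the expressed share was 68.9%, 68.4%, 65.2% and 68.3%, and the median of the expressed genes was 10.9, 10.8, 10.1 and 10.5 FPKM. For the 1395 genes of other sequences, outside the named arms, the share was 39.5% and the median 7.69 FPKM. Gene models on chromosome 4 were also longer, with a median span of 6632 bp against 1513 bp on chromosomes 2 and 3. The 2401 genes of the X chromosome had an expressed share of 69.6% and a median of 10.1 FPKM, which was 0.957 of that on chromosomes 2 and 3 (95% range from resampling genes, 0.895 to 1.04). This range covers the choice of genes and includes 1, and the ratio was 1.05 for genes at 0.1 FPKM or more.

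In virilis, whose genes lie on numbered scaffolds, the 4 scaffolds that shared paired symbols with the yakuba X held 2139 genes with a median of 11.2 FPKM among those expressed. The 8 scaffolds paired with chromosomes 2 and 3 held 10564 genes with a median of 11.9 FPKM, so that the ratio was 0.937 (0.888 to 1.01). The scaffold of ATPsyn-beta, the only paired gene on yakuba chromosome 4, held 93 genes, of which 88.2% were expressed, with a median of 25.7 FPKM. This assignment rests on 1 gene. The same holds for scaffold_12932 among those paired with the X, and for scaffold_10324 and scaffold_12758 among those paired with chromosomes 2 and 3.

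**Figure D4:**
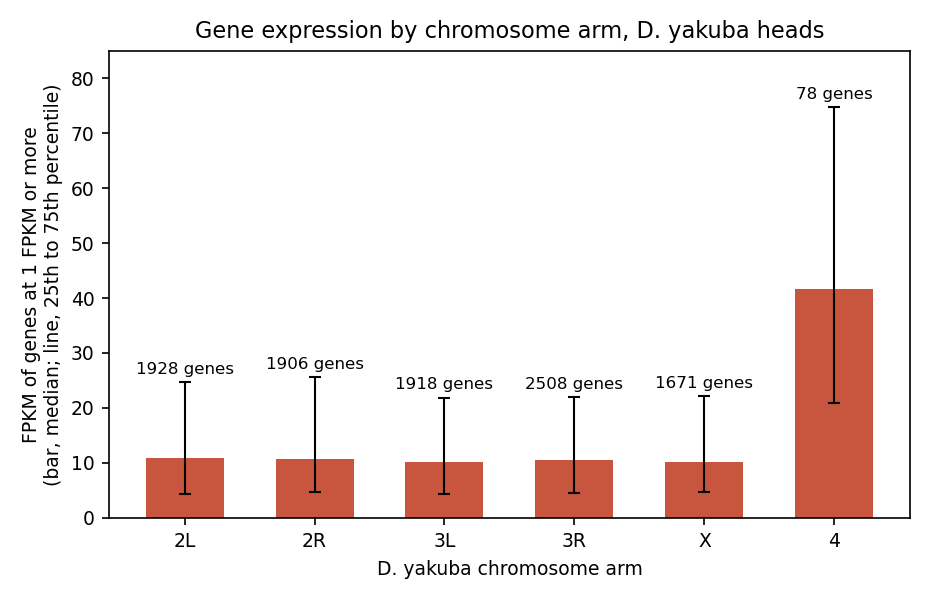
Median FPKM (bars) and 25th to 75th percentile (lines) of yakuba genes at 1 FPKM or more, by chromosome arm, with the number of such genes above each line. Chromosome 4 stood at 41.6 FPKM, and the other arms lay between 10.1 and 10.9 FPKM.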

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

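Pseudocounts of 0.1 and 5 FPKM, other centrings, TPM, other minimum levels and spans within 1.5 times were chosen beforehand, and the settings without models under 300 bp, with unmatched or symbol-only random lists and with older spellings of symbols were chosen after seeing the data. Ratios between species were recomputed for the 15 pairs named in each direction and for lists of 3 or more pairs under both pseudocounts, no centring, ribosomal centring and TPM, and none of these changed sign, except that centring on the ribosomal protein genes sets their own median to 0 by construction. The median removed, of pairs at 1 FPKM or more in both libraries, was -0.20, and it was -0.36 over the ribosomal protein genes and -0.40 after TPM. Counts past 4-fold towards virilis were 2 with ribosomal centring, 5 with no minimum and 0 with a 30 FPKM minimum, against 1, and counts towards yakuba were 1 with a pseudocount of 5 FPKM and 1 with a 30 FPKM minimum, against 3, and without models under 300 bp, which removes MtnC, they were 2. The pseudocount of 5 FPKM shrinks the ratios of low genes, and it moved dhd to -1.86, while a higher minimum leaves fewer genes. With that pseudocount MtnC was also no longer past 4-fold, and the ratio of Mal-A5 became smaller but stayed past 4-fold. With only members at 1 FPKM or more, which removes the low members by construction, medians were 144 FPKM for the virilis fat body list, 2.81 and 1.99 FPKM for oogenesis in virilis and yakuba, and 10.4 FPKM for the yakuba digestive genes. Pearson r stayed between 0.902 and 0.951, the yakuba X ratio was 1.05 at a minimum of 0.1 FPKM, and the chromosome 4 ratio ranged from 2.71 to 5.43 around 3.94. Merging equal names and leaving out names of non-coding RNAs changed nothing, since neither occurred. No paired analysis was possible because each species has 1 library and no result comes from a test, and no library could be left out. Depth limits values near 0.0424 FPKM in virilis and 0.0476 FPKM in yakuba per kb, so that values such as 0.0864 FPKM for nos in virilis rest on few fragments.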

Other observations

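Further gene families, chosen after their names and values had been seen, add to the picture of the heads. The 40 odorant-binding protein genes with a symbol in virilis ran from 0 to 4081 FPKM, and 8 were at 100 FPKM or more. The virilis actin genes ActC2, ActE1, ActD1 and ActE2 had 2199, 1159, 190 and 121 FPKM, and the 5 troponin C genes had a median of 91.9 FPKM. The alcohol dehydrogenase genes Adh1 and Adh2 of virilis had 1979 and 1537 FPKM, values that are uncertain where the copies share reads, and Adh of yakuba had 4341 FPKM. The 6 copies of Hsp70 in virilis lay between 178 and 227 FPKM, and their separate values are uncertain for the same reason. The 4 cecropin genes of virilis, which encode antimicrobial peptides, had 0.409 to 1.43 FPKM.

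The 10 genes named as maltases had low medians in both libraries, 0.696 FPKM in virilis and 0.637 FPKM in yakuba, and Mal-A5 of virilis and Mal-B2 of yakuba were the highest at 23.3 and 35.3 FPKM. The 5 yakuba genes named for male accessory gland proteins had 0 to 3.11 FPKM in these female heads, and 4 of them were under 1 FPKM. With no minimum level, the genes y, plu and SuUR were also past 4-fold towards virilis, at 8.71, 3.90 and 9.77 FPKM against 0.207, 0.136 and 1.84 FPKM, though the models of y differed in span by over 1.5 times, and MtnD had 8.39 FPKM in virilis and was listed at 0 in yakuba.

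The tests on muscle genes described next were chosen after the result had been seen, and those on chromosome 4 and on short models were written down before theirs. Genes on yakuba chromosome 4 had a median of 41.6 FPKM. Matching on decile of genomic span did not account for this. The median was at percentile 100 of 10000 random sets of expressed genes from other arms so matched, whose highest median was 21.5 FPKM. Span includes introns, so the exonic length of the models was not matched, and spans within the top decile can still differ. The virilis scaffold linked to this chromosome by ATPsyn-beta also stood high, at 25.7 FPKM against 9.72 to 17.4 FPKM in the central 95% of span-matched sets, which is consistent with a property of the same chromosome in both species. Both values come from single libraries and the scaffold was assigned by 1 gene, so a shared chromosomal property remains a hypothesis, and mapping bias was not tested.

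The muscle genes Mhc, Mlc1 and wupA were higher in virilis by a median log2 ratio of 1.67. None of the scalings tried removed this difference, and their median was 1.48 or more under each. The shifts removed by these scalings ran only from 0 to -0.40 on the log2 scale, too little to cancel 1.67. This outcome was therefore fixed in advance, and other errors of scaling were not tested. More muscle tissue in the virilis head sample is a candidate explanation. The lowest of the 3 ratios, 1.47 for Mhc, restates the observation and does not bear on it. This explanation cannot be told apart from a species difference in muscle gene expression or in gene models, because species and library are the same factor here.

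Short gene models were common among the highest values of virilis, where 8 of the 51 models at 1000 FPKM or more (15.7%) had spans under 300 bp against 4.13% of all models. In yakuba the share was closer to that of all models, with 5 of 57 (8.77%) against 5.94%, and neither difference was tested. They were also common at the other end, since 35.5% in virilis and 43.8% in yakuba of models under 300 bp were listed at 0 against 3.56% and 6.29% of models of 1000 to 2000 bp. If few fragments fit in models near the fragment length, FPKM could be unstable there and spread more widely. The SD of log2 FPKM of models above 0 was not wider for short models. It was 0.960 times that of the longer models in yakuba (0.905 to 1.01 from resampling genes) and 0.999 times in virilis (0.929 to 1.06). By the rule written beforehand, a ratio of 1 or less in either library counted against this explanation. Both ranges include 1, though, and the SD leaves out the models at 0, so the test cannot decide. No biological explanation was tested.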
